A study of Mus musculus with 4 samples.

How the data were processed

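Aortas of C57BL/6 mice were profiled by small RNA sequencing in 2 Sham and 2 CKD libraries. Per the labels' protocols, RNA was extracted with Trizol, 4 samples were pooled for each library, RNA of 18 to 30 nucleotides was cut from a gel, and adaptors were ligated to both ends before amplification. Adaptor ligation is known to capture some small RNA sequences better than others, and no molecular identifiers are described, so reads are not independent molecules. Bowtie, with no version given, and the build GRCm38 are named per the submitters' processing notes. The miRNA annotation, the counting, the way unannotated entries were made and the handling of reads that match several miRNAs are not given in the sources used here.

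Each deposited file lists 1152 entries, 1079 with miRNA names and 73 with numbered names starting with Novel_. The labels do not state the unit. The deposited values have 2 decimals and sum to about 1000000 in each library, so they were read as counts per 1000000 (CPM). In 3 of the 4 files the names stand above the values in a single column, which is a deposited layout outside the usual kinds (unit other), and names were paired with values by position. Among entries with a mean CPM of at least 1, 9 groups with 22 members hold equal values in all 4 libraries, each within 1 miRNA family, as a pairing by position should give for shared sequences. Mature sequences were not used here to check this. miR-199a-3p with miR-199b-3p is such a pair, and their reads cannot be told apart. In all 4 libraries 100% of the non-zero values were whole multiples of 1 read within 0.005 CPM. This gave totals of 17520690 and 16878392 reads in Sham and 17532748 and 16658810 reads in CKD. These totals cover the listed entries, not all sequenced reads.

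The design was fixed before the data were examined, as were the lists, the rule for named miRNAs and the alternatives, except where the text says otherwise. It foresaw an edgeR test for counts, and limma on log2(value + 1) for normalized values. The deposited CPM called for the second. limma was run on log2(CPM + 1) for the 479 entries with a mean CPM of at least 1, 41 of them without a miRNA name, with the group as the only term and a two-sided Benjamini-Hochberg adjusted p threshold of 0.05. The plan worded the trend and robust options together, which left the trend setting open. A mean-variance trend was used, and without it 402 entries were called as well. Differences on the log2(CPM + 1) scale understate the change of low entries. TMM factors from the recovered reads, applied to the CPM, were added after the data were seen, as was edgeR's quasi-likelihood test on the recovered reads, which called 39 entries, 10 higher and 29 lower. TMM and edgeR shared 9 higher and 27 lower calls. TMM multiplied the effective library sizes by 0.479 and 0.696 in Sham and by 1.81 and 1.66 in CKD, so it assumes that most miRNAs were unchanged.

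The 16 fixed lists were tested with camera at a preset correlation of 0.01, with at least 3 tested members needed, which left 15. An estimated correlation and fry were the alternatives. miRNAs were named by a fixed rule. It took up to 12 per direction past the threshold with a mean CPM of at least 10 and both CKD libraries on the same side of both Sham libraries, filled to 6 with the smallest unadjusted p. It added the 10 most abundant, up to 4 called members of each list or its 2 most abundant, and a set of vascular and blood miRNAs, 74 in all. A count of 0 was given a floor of 3 reads per library, and shares have Wilson 95% intervals. Other alternatives were median-of-ratios and upper-quartile scaling, library totals without the 10 most abundant miRNAs, no filter, a mean CPM of at least 10, pseudocounts of 0.1 and 10, limma voom, DESeq2, the replicate number as a block, summed near-identical miRNAs, a log2 threshold of 1 and leaving out each library. Library totals alone and limma trend on log2(CPM + 1), both planned, coincide here with the test used.

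Libraries of one group differed by more than counting noise (chi-square per degree of freedom 515 between the Sham libraries and 367 between the CKD libraries), so neither pair was treated as 1 library deposited in duplicate. This does not show that they are biological replicates, since separate preparations of 1 pool would differ too. Pearson correlations of log2 values across entries, which are not independent replicates, were 0.992 and 0.981. No batch is given in the labels. The tests were tested on simulated counts with 200 changed entries. With miR-143-3p simulated at 0.3 of its Sham level, 44 of 291 unchanged entries were called on the deposited scale, where their median was 0.47, and 6 of 291 with TMM scaling. Both simulated groups started from the mean of the 4 libraries, and the simulated shift was smaller than the observed median of 1.34. Libraries of a group had no offset, and as many entries changed upward as downward, which meets the TMM assumption. These counts of wrong calls therefore need not hold for the real libraries. TMM scaling recovered 66% of changes of 2-fold and 100% of changes of 4-fold upward in that simulation. Loci were taken from a GENCODE annotation of GRCm38, the build the notes name. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.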

Results

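Small RNA of 18 to 30 nucleotides was sequenced from the aortas of 12-week C57BL/6 mice, a common inbred laboratory strain, to profile microRNAs (miRNAs) in vascular calcification induced by chronic kidney disease (CKD). There were 4 libraries, 2 labelled Sham and 2 labelled CKD, and each was made from a pool of 4 samples. In the labelled model, kidney tissue was removed in a pair of operations 1 week apart, and the mice then received a 2% phosphate diet and 0.45% NaCl in their water for 4 weeks. The labels word this treatment identically for both groups, so how the Sham mice were handled is not given in the sources used here. The recovered totals were 17520690 and 16878392 reads in the Sham libraries and 17532748 and 16658810 in the CKD libraries, so 3 reads corresponded to between 0.171 and 0.180 CPM (counts per 1000000). Of the 1152 entries listed, 730 and 795 had reads in the Sham libraries, and 963 and 940 in the CKD libraries.

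The aortic miRNA pool was dominated by miR-143-3p, a product of the miR-143/145 cluster that maintains the contractile state of smooth muscle, and its share was far smaller in CKD. It made up 76.2% ± 5.16 (SD, n = 2) of reads in Sham and 41.0% ± 0.250 (SD, n = 2) in CKD, a difference of -35.2 percentage points. The single libraries held 79.8% and 72.5% in Sham, and 41.1% and 40.8% in CKD. The Wilson 95% interval of the first Sham library was 79.80% to 79.84% and that of the first CKD library 41.11% to 41.16%. Such intervals and the floors of 3 reads cover counting error only. miR-145a-5p, from the same cluster, went from 4.03% ± 0.977 (SD, n = 2) to 7.19% ± 0.548 (SD, n = 2). The next most abundant were miR-140-3p (2.79% and 3.34% of reads in Sham and CKD), miR-26a-5p (1.50% and 4.16%) and miR-125b-5p (1.20% and 3.55%). The 10 most abundant miRNAs together held 89.4% ± 2.45 (SD, n = 2) in Sham and 69.5% ± 0.124 (SD, n = 2) in CKD, a difference of -19.9 points. In GRCm38, Mir143 lies on chromosome 18 from 61649196 to 61649258 and Mir145a on chromosome 18 from 61647825 to 61647894, neither of them inside an annotated gene on the same strand.

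**Figure D1:**
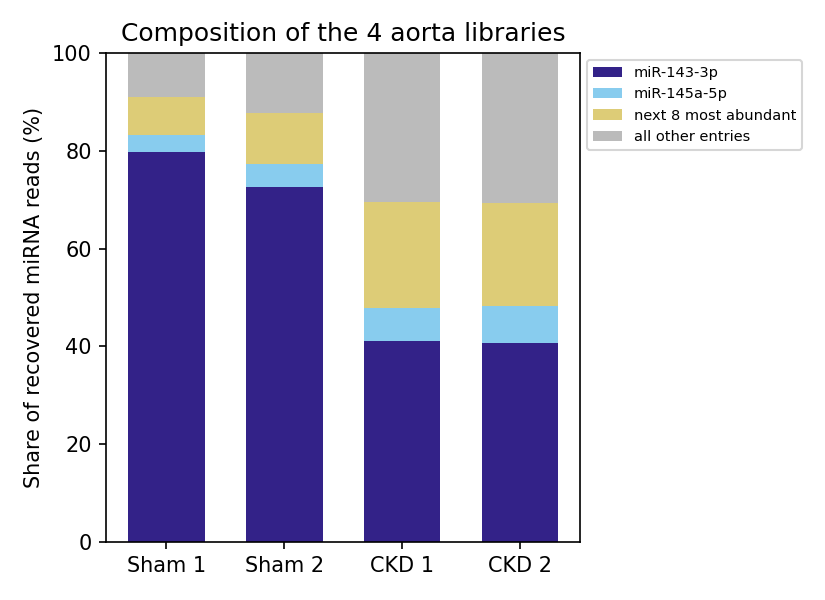
Stacked bars give the percentage of recovered reads in each of the 4 libraries taken by miR-143-3p, by miR-145a-5p, by the next 8 most abundant miRNAs and by all other entries. miR-143-3p takes 79.8% and 72.5% in the Sham libraries and 41.1% and 40.8% in the CKD libraries.

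On the deposited scale, where each library sums to a fixed total, nearly every other miRNA was higher in CKD. Entries other than miR-143-3p held 20.2% and 27.5% of reads in the Sham libraries, and 58.9% and 59.2% in the CKD libraries. With the total fixed, a smaller share of miR-143-3p by itself raises the values of the rest. This scale therefore cannot tell a fall of miR-143-3p from a rise of the other miRNAs. The median log2 difference of the 479 tested entries was 1.34, a 2.53-fold increase, and 437 of them were higher in both CKD libraries than in both Sham libraries. Chance gives 16.7% for a single entry. The entries share the shift of their library and are not independent, so the count is not separate evidence from each. By limma with Benjamini-Hochberg adjustment, 402 entries passed the threshold, 397 higher and 5 lower, so 98.8% of calls were higher. After trimmed-mean (TMM) scaling, which takes out the shift shared by most miRNAs, 37 passed, 9 higher and 28 lower, so 24.3% of calls were higher. Directions below are therefore given relative to that shared shift, and the deposited difference or CPM is given for each named entry past the threshold with TMM scaling. The TMM count was fragile: without Sham 1, Sham 2, CKD 1 or CKD 2 it was 7, 13, 8 and 5, and none was lower without either CKD library. The p-values measure only the spread between these pooled libraries, and 2 libraries per group leave 2 residual degrees of freedom. limma adds to these by borrowing variance across entries, which are not independent, so its p-values are smaller than 2 degrees of freedom alone could give.

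**Figure D2:**
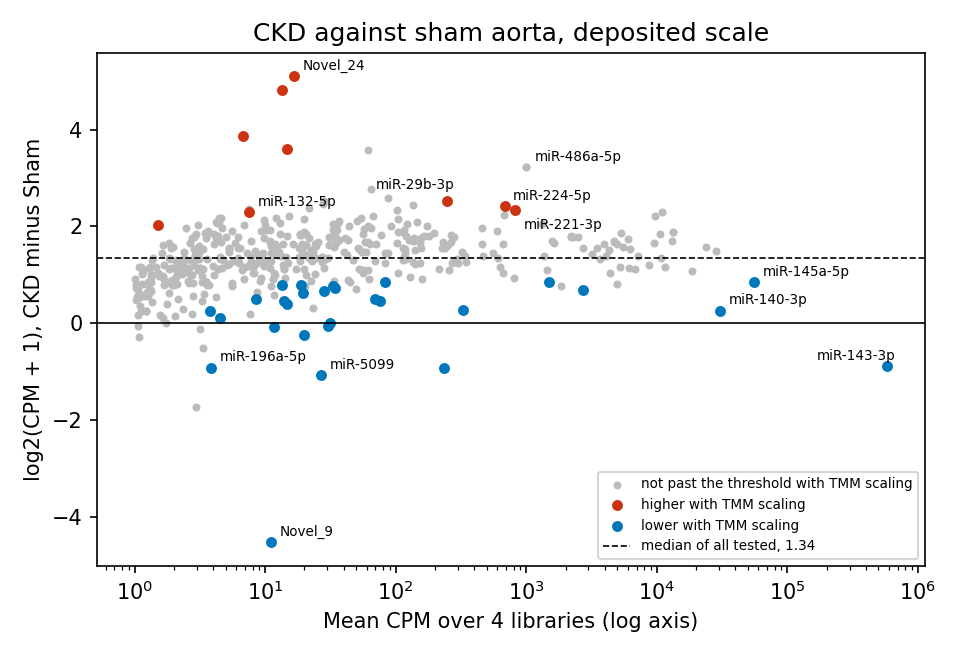
Each point is 1 of the 479 tested entries, with mean CPM over the 4 libraries on a log axis and the log2(CPM + 1) difference, CKD minus Sham, on the deposited scale. The dashed line is the median of 1.34, and the 28 entries that were lower with TMM scaling (blue) lie below it. Some of them lie above 0, such as miR-140-3p at 0.26, whose direction differs between the scales. Others have negative values on both scales, such as let-7i-3p at -0.24, which did not pass on the deposited scale (limma adjusted p = 0.48). The 9 that were higher (red) lie above the line.

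A set of 5 entries fell on the deposited scale itself, and fell further relative to the shared shift: miR-143-3p, miR-5099, miR-196a-5p, Novel_9 and Novel_47. For miR-143-3p the log2 difference was -0.89 on the deposited scale (SE 0.11, limma adjusted p = 2.5e-04) and -2.48 relative to the shift (SE 0.24, limma adjusted p = 0.012). The deposited call for miR-143-3p was lost without CKD 1 (limma adjusted p = 0.078) or CKD 2 (limma adjusted p = 0.13), at log2 differences of -0.90 and -0.89. miR-5099 went from 36.6 ± 3.68 CPM to 16.9 ± 0.255 CPM (SD, n = 2), with a log2 difference of -2.58 relative to the shift, and its deposited call was likewise lost without CKD 1 (limma adjusted p = 0.22) or CKD 2 (limma adjusted p = 0.25), at deposited log2 differences of -1.08 and -1.05 against -1.07 with all libraries. miR-196a-5p, encoded within the Hox gene clusters, was chosen after its values were seen. It went from 5.38 ± 0.389 to 2.37 ± 0.120 CPM (SD, n = 2), with a log2 difference of -2.13 relative to the shift. Novel_9, an entry with no miRNA name, had 21.6 and 22.7 CPM in the Sham libraries and no reads in either CKD library, on the deposited scale at least 126-fold lower against a floor of 3 reads per library. Its log2 difference relative to the shift was -5.30. Novel_47 lay at -0.93 on the deposited scale and -2.51 relative to the shift, close to miR-143-3p on both. Whether Novel_47 fell separately from miR-143-3p was not tested.

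Among annotated miRNAs that rose relative to the shift were miR-29b-3p, a repressor of collagen and other matrix genes, and miR-221-3p, known for promoting smooth muscle proliferation. miR-29b-3p went from 72.7 ± 20.3 to 418 ± 78.0 CPM (SD, n = 2), with a log2 difference of 0.95 (SE 0.14, limma adjusted p = 0.038), and 2.52 on the deposited scale. miR-221-3p went from 274 ± 72.1 to 1371 ± 17.9 CPM (SD, n = 2), with 0.76 relative to the shift (SE 0.12, limma adjusted p = 0.039) and 2.34 on the deposited scale. Both missed the threshold with upper-quartile scaling (limma adjusted p = 0.052 for each). miR-224-5p and miR-132-5p, chosen after their values were seen, also rose, by 0.83 and 1.02 relative to the shift, and by 2.41 and 2.30 on the deposited scale. In GRCm38, Mir29b-1 lies on chromosome 6 from 31063023 to 31063093 and Mir221 on chromosome X from 19146294 to 19146388, neither inside a gene on the same strand, and Mir224 lies on chromosome X from 72261031 to 72261112 in an intron of Gabre. A second copy, Mir29b-2, lies on chromosome 1 from 195037040 to 195037120 and overlaps an exon of A330023F24Rik.

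The highest deposited differences among annotated miRNAs belonged to blood and liver miRNAs and varied strongly between libraries. miR-486a-5p and miR-486b-5p, red-cell miRNAs listed with identical values, had 76.9 and 212 CPM in Sham and 445 and 3266 CPM in CKD. miR-122-5p, the main hepatocyte miRNA, had 1.43 and 25.5 CPM in Sham and 161 and 56.0 CPM in CKD. miR-92a-3p, also abundant in red cells, had 5.71 and 19.9 CPM in Sham and 30.5 and 205 CPM in CKD. All 4 rose on the deposited scale (limma adjusted p from 0.0032 for miR-122-5p to 0.0054 for miR-92a-3p) and none passed with TMM scaling. miR-34c-5p, a p53 target that slows proliferation, rose on the deposited scale by 2.59 (SE 0.38, limma adjusted p = 6.8e-04), and lay at 1.04 relative to the shift (SE 0.29, limma adjusted p = 0.11). miR-708-5p (2.53), miR-139-5p (2.47) and miR-15b-5p (2.45) likewise rose on the deposited scale. Relative to the shift they lay at 1.05 (SE 0.32), 0.98 (SE 0.21) and 0.89 (SE 0.48), without passing the adjusted threshold.

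The contractile smooth muscle list held members on both sides of the shift. On the deposited scale 3 of its 5 members rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. Relative to the shift, miR-143-3p (-2.48) and miR-145a-5p (-0.73, SE 0.13, limma adjusted p = 0.044) fell, although miR-145a-5p rose by 0.85 on the deposited scale. miR-143-5p lay at -0.81 (SE 0.18, limma adjusted p = 0.08), miR-145a-3p at 0.22 and miR-145b at 0.65, none of them past the threshold, and the value of miR-143-5p was 0.77 on the deposited scale. Adjusted over the list alone, 1 member was higher and 3 lower relative to the shift. Camera, which compares a list with all other tested miRNAs, gave an adjusted p of 0.16 on the deposited scale and 0.3 with TMM scaling for this list (limma).

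miRNAs described as opposing and as promoting smooth muscle calcification were mostly higher on the deposited scale, and the lists were not tested against each other. Of 18 tested opposing members 17 rose on the deposited scale, and of 10 promoting members all 10 rose, with the same counts adjusted over the list alone. Relative to the shift their medians were 0.10 and 0.18, with miR-29b-3p the only opposing and miR-221-3p the only promoting member past the threshold over all tested. Adjusted over the list alone, 2 opposing members and 1 promoting member were higher. miR-204-5p, which represses the osteogenic factor Runx2, had 17.4 and 20.4 CPM in the Sham libraries and 81.3 and 96.8 CPM in the CKD libraries, and lay at 0.63 relative to the shift (SE 0.20, limma adjusted p = 0.14). miR-223-3p, a myeloid miRNA, lay at 0.78 relative to the shift (limma adjusted p = 0.11), miR-133a-3p at -0.64 and miR-26a-5p at -0.09, although the last pair rose on the deposited scale. Camera gave adjusted p of 0.16 and 0.34 on the deposited scale and 0.17 for both lists with TMM scaling (limma).

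Fibroblast and matrix miRNAs were the only list that camera called with TMM scaling. On the deposited scale 13 of its 15 members rose and 2 did not pass, with the same counts adjusted over the list alone. Relative to the shift the median was 0.36, 13 members lay above 0, and camera called the list higher (limma adjusted p = 0.03), a call lost with an estimated correlation (adjusted p = 0.54). The identical miR-199a-3p and miR-199b-3p, at 0.30, entered these counts and the test as 2 members. Over all tested, 1 member was higher (miR-29b-3p) and 1 lower (miR-199b-5p, -1.31), and adjusted over the list alone 5 were higher and 2 lower. The deposited difference of miR-199b-5p was 0.27 (limma adjusted p = 0.54), so its direction differs between the scales. miR-29a-3p lay at 0.71 (SE 0.14, limma adjusted p = 0.053), miR-214-3p at 0.66 and miR-21a-5p, a profibrotic miRNA, at 0.63 (SE 0.19, limma adjusted p = 0.13). The stress and senescence list had all 13 tested members higher on the deposited scale, with a median of 0.29 relative to the shift, none called over all tested and 2 higher adjusted over the list alone (camera adjusted p = 0.2, limma). Epithelial (median 0.37) and neural (0.47) lists had medians above that of the matrix list. The erythroid median was 0.33, with the identical miR-486a-5p and miR-486b-5p counted as 2 members. With that pair counted once, the middle erythroid value would be that of miR-451a, at 0.06.

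Camera called none of the testable lists of other cell types on either scale, while fry with TMM scaling, which tests a list against no change and not against other miRNAs, called striated muscle lower and neural higher (limma adjusted p = 0.021 for each). Camera gave both lists an adjusted p of 0.54 with an estimated correlation (limma, TMM scaling). Leukocyte miRNAs had 10 of 12 members higher on the deposited scale and a median of 0.00 relative to the shift (camera adjusted p = 0.46, limma), with miR-142a-3p at -1.18 and miR-511-3p at 0.77. Both tested endothelial members rose on the deposited scale, and miR-126a-3p, the main endothelial miRNA, lay at 0.05 and miR-126a-5p at 0.11 relative to the shift. This list was too short for a set test. All 6 erythroid members rose on the deposited scale (camera adjusted p = 0.45 with TMM scaling, limma), with the identical miR-486a-5p and miR-486b-5p counted as 2. miR-451a had 130 and 574 CPM in Sham and 510 and 1425 CPM in CKD. Striated muscle miRNAs had 3 of 6 members higher on the deposited scale, 2 adjusted over the list alone, and all 6 lay below 0 relative to the shift, with a median of -0.33 (camera adjusted p = 0.13, limma) and miR-1a-3p at -0.86. Adipocyte-associated miRNAs had 9 of 12 higher and 1 lower on the deposited scale, 10 and 1 adjusted over the list alone, and a median of -0.16 relative to the shift (camera adjusted p = 0.43, limma). Epithelial miRNAs had 10 of 11 higher on the deposited scale (camera adjusted p = 0.13 with TMM scaling, limma), with miR-183-5p at 1.13 relative to the shift. All 7 tested neural miRNAs rose on the deposited scale (camera adjusted p = 0.17 with TMM scaling, limma), with miR-9-3p at 0.76. In these lists no member other than miR-196a-5p passed over all tested with TMM scaling, while adjusted over the list alone 2 striated muscle and 2 adipocyte-associated members were lower.

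Camera called none of the families and clusters on the deposited scale or with TMM scaling, and the let-7 and Dlk1 to Dio3 lists were called in opposite directions under other settings. With upper-quartile scaling both were lower (limma adjusted p = 0.043 for each), and without a filter on low values both were higher (0.038 and 0.0015). An estimated correlation was run only with TMM scaling and on the deposited scale. There camera called neither (limma adjusted p = 0.7 and 0.54 with TMM scaling, 0.99 for each on the deposited scale). All 9 let-7 and miR-98 members, known repressors of proliferation, rose on the deposited scale, yet all 9 lay below 0 relative to the shift, with a median of -0.37 (camera adjusted p = 0.061, limma), none called over all tested and 1 lower adjusted over the list alone. The Dlk1 to Dio3 imprinted cluster, a large group of maternally expressed miRNAs on chromosome 12, had 40 of 51 tested members higher on the deposited scale, 39 adjusted over the list alone. Relative to the shift 35 of its members lay below 0, 6 fell over all tested and 7 adjusted over the list alone, which also made 1 higher, and the median was -0.11 (camera adjusted p = 0.061, limma). Among the 6 were miR-381-3p (-1.59) and miR-299a-3p (-1.09), both chosen after their values were seen, with deposited differences of -0.06 and 0.39. The proliferation-linked clusters of miR-17, miR-106a and miR-106b had 12 of 15 members higher on the deposited scale and a median of 0.18 relative to the shift (camera adjusted p = 0.3, limma). All 9 members of the miR-15 and miR-16 seed family rose on the deposited scale, with a median of -0.01 relative to the shift (camera adjusted p = 0.68, limma). The counts on the deposited scale were equal adjusted over the list alone for these families, for the stress list and for the leukocyte, endothelial, erythroid, epithelial and neural lists. None of the miR-15 and miR-16 family and the miR-17, miR-106a and miR-106b clusters had a member past the threshold with TMM scaling, over all tested or adjusted over the list alone.

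Camera called 0 of the 15 testable lists on the deposited scale (limma, smallest adjusted p = 0.16), with 4 at an unadjusted p under 0.05, and fry called 0. With an estimated correlation 0 lists were called on either scale. On the deposited scale the sign of camera's statistic was negative, against a positive list median, for the contractile (limma adjusted p = 0.16), striated muscle (0.34), adipocyte-associated (0.34), erythroid (0.92), miR-17 cluster (0.92) and Dlk1 to Dio3 (0.92) lists, none of them called. The erythroid and miR-17 cluster medians of 1.88 and 1.67 lay above the median of 1.34 of all tested entries, so for these the sign of the median and of the test differ. With TMM scaling fry called 3 lists, the third being Dlk1 to Dio3, lower (limma adjusted p = 0.021), which camera gave an adjusted p of 0.54 with an estimated correlation.

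**Figure D3:**
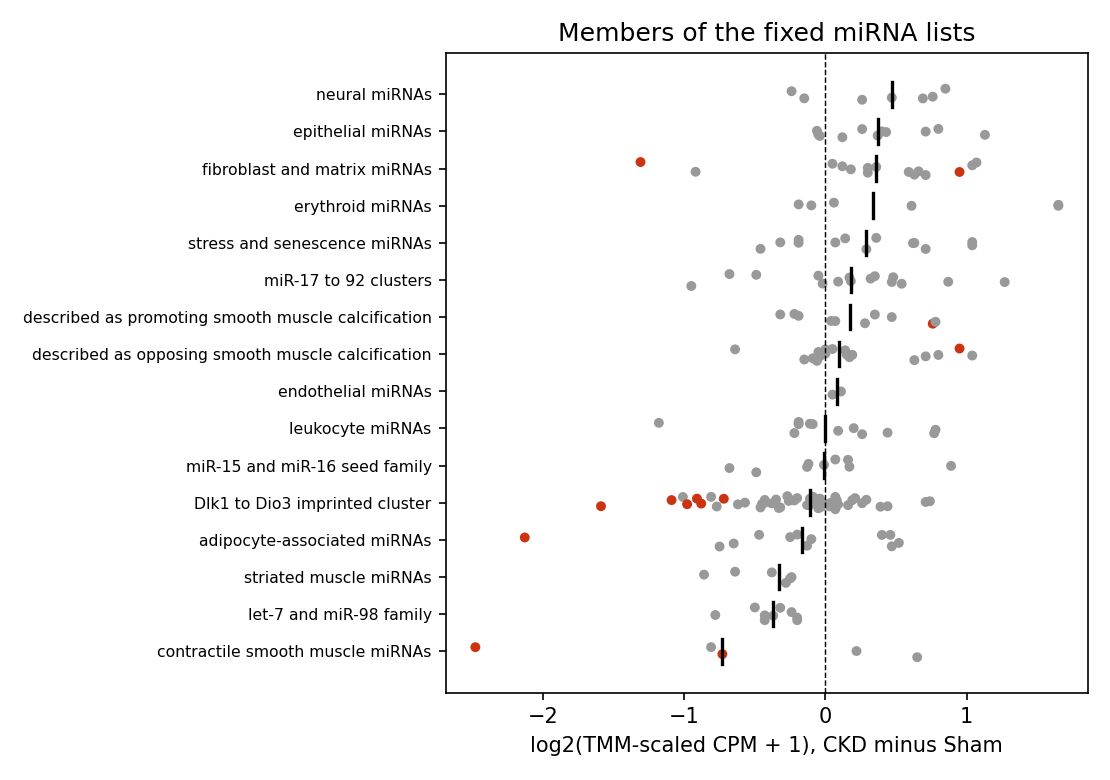
Each point is a tested member of a fixed list, placed by its log2 difference, CKD minus Sham, after TMM scaling, with red points past the threshold over all tested, short bars at list medians and vertical jitter for display only. The fibroblast and matrix list has a median of 0.36 and the let-7 and miR-98 family a median of -0.37, which is 1.21 on the deposited scale, where its members are higher.

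Ratios within a library need no scaling, and they showed the strands of several hairpins moving apart between the groups. The miR-143-3p to miR-143-5p ratio was 628 and 509 in the Sham libraries and 157 and 202 in the CKD libraries, a log2 change of -1.67 (SE 0.24, n = 2 per group). The ratio of miR-143-3p to miR-145a-5p changed by -1.75 (SE 0.33), and that of miR-145a-5p to miR-145a-3p by -0.96 (SE 0.19). The ratio of miR-140-3p, an miRNA of cartilage and smooth muscle, to miR-140-5p changed by -0.78 (SE 0.09). In the other direction, miR-21a-5p over miR-21a-3p changed by 2.00 (SE 0.26) and let-7i-5p over let-7i-3p by 1.06 (SE 0.15). Over 55 hairpins with both strands at a mean CPM of at least 10, which leaves out miR-21a, the median absolute change between groups was 0.37, against 0.15 between the Sham libraries and 0.19 between the CKD libraries. The single-strand ratios named here were chosen after their values were seen, and were not tested beyond their standard errors.

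**Figure D4:**
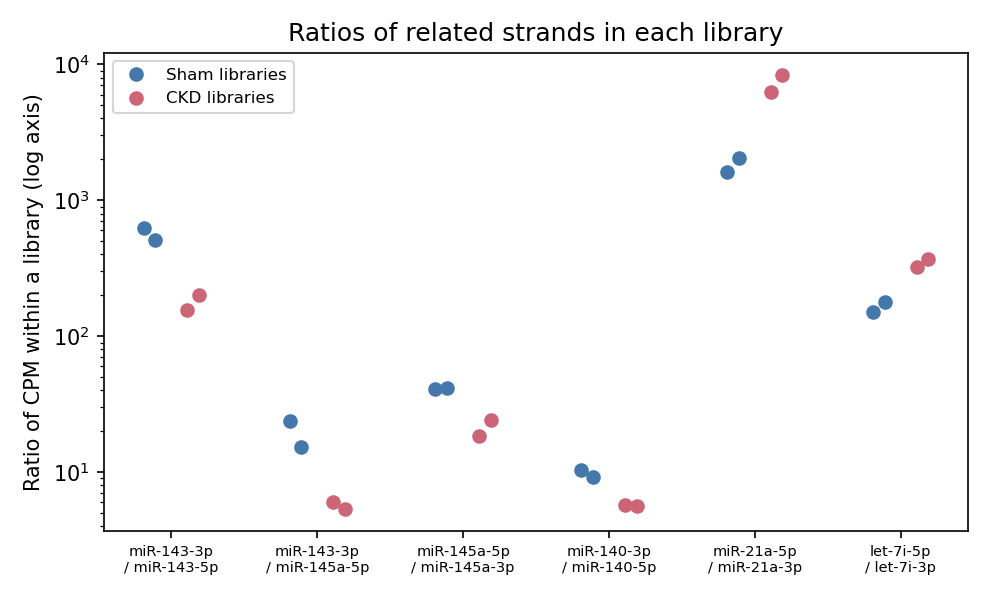
Points give the ratio of CPM between a pair of miRNA strands within each library on a log axis, with Sham libraries in blue and CKD libraries in red. The miR-143-3p to miR-143-5p ratio is 628 and 509 in Sham and 157 and 202 in CKD, and the miR-21a-5p to miR-21a-3p ratio is higher in both CKD libraries than in both Sham libraries.

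Entries without a miRNA name gave the most extreme values. Of 41 such entries tested, 5 were higher and 4 lower with TMM scaling. Novel_24 and Novel_28 had no reads in either Sham library and 33.3 ± 1.36 and 27.1 ± 1.67 CPM in CKD (SD, n = 2), on the deposited scale at least 191-fold and at least 155-fold higher against the floor of 3 reads per library. Relative to the shift their log2 differences were smaller, at 4.34 and 4.06 against 5.10 and 4.81 on the deposited scale. Novel_38 went from 1.40 ± 0.368 to 27.9 ± 4.07 CPM (SD, n = 2). Novel_47 went from 306 ± 26.9 to 160 ± 4.55 CPM (SD, n = 2), a call on the deposited scale (limma adjusted p = 0.047) that was lost without Sham 1 (0.052), CKD 1 (0.31) or CKD 2 (0.26), at log2 differences of -0.84, -0.90 and -0.96 against -0.93 with all libraries.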

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

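The TMM, edgeR, untrended, annotated-only and TMM leave-one-out tests were chosen only after the result was seen, and the other alternatives were planned. Against 402 calls (397 higher, 5 lower), the count was 37 (9 higher, 28 lower) with TMM scaling, 32 (9, 23) with median-of-ratios scaling, 29 (5, 24) with upper-quartile scaling and 28 (9, 19) without the 10 most abundant miRNAs. It was 39 (10, 29) in edgeR and 81 (32, 49) in DESeq2. These scalings remove the shared shift by construction. A mean CPM of at least 10 gave 241 (237 higher), with 265 entries tested, and a log2 threshold of 1 left 2 lower. Leaving out a library gave 143 to 392 calls, 140 to 387 higher and 3 to 6 lower on the deposited scale, where the lone library is assumed to vary like the other group, with 143 without CKD 1, 241 without CKD 2, 296 without Sham 1 and 392 without Sham 2. With TMM scaling it gave 5 to 13 calls (7 without Sham 1), 3 to 8 higher and 0 to 9 lower. The 0 lower calls came without CKD 1 and without CKD 2, where limma had 96 and 108 entries of either direction at an unadjusted p under 0.05. The cause of the drop was not tested. No filter (313), pseudocounts of 0.1 (395) and 10 (413), voom (399), annotated entries alone (390), summed near-identical miRNAs (315) and a log2 threshold of 1 (348) stayed within 1.5 times the count.

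The replicate numbers of the labels name no shared animal or day. With the replicate block the count was 352 (347 higher, 5 lower) on the deposited scale and 10 (4 higher, 6 lower) with TMM scaling, and camera called 3 lists on the deposited scale. Compared with other miRNAs the contractile list was lower, and the calcification-opposing and matrix lists were higher (limma adjusted p = 0.038 for each). With an estimated correlation and no block each had an adjusted p of 0.99 (limma). The deviations of same-numbered libraries correlated at 0.10 on the deposited scale and 0.12 with TMM scaling over only a pair of numbers, so the numbers are not taken to pair the libraries.

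Against 0 lists on the deposited scale, camera called 1 with TMM scaling, 1 with median-of-ratios scaling, 3 with upper-quartile scaling, 2 without the 10 most abundant miRNAs and 6 without a filter, and fry with TMM scaling called 3. The direction turned between these settings. let-7 was lower with upper-quartile scaling (limma adjusted p = 0.043), without the 10 most abundant miRNAs (0.023) and with TMM scaling without CKD 2 (4.5e-04), and Dlk1 to Dio3 was lower with upper-quartile scaling (0.043). Without a filter all 6 called lists were higher, let-7 (0.038) and Dlk1 to Dio3 (0.0015) among them, on the deposited scale and over 1152 entries. Leaving out a library gave 0 on the deposited scale and 0 to 2 with TMM scaling, where the matrix list passed without Sham 1 or CKD 2 and not without Sham 2 or CKD 1. The change in the share of the 10 most abundant miRNAs was -21.64 to -18.17 points. Without CKD 1, CKD 2 and Sham 1, 38, 25 and 9 of the 74 named miRNAs no longer passed on the deposited scale. miR-142a-3p, at 1.12 without Sham 2, turned to -0.48 without Sham 1 and -0.02 without CKD 2.

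Directions of the named miRNAs reversed as follows. With TMM scaling the log2 differences became -0.32 for miR-98-5p, -0.52 for miR-27b-3p, -0.09 for miR-26a-5p, -0.86 for miR-1a-3p, -0.01 for miR-15a-5p, -0.73 for miR-145a-5p, -1.18 for miR-142a-3p, -1.33 for miR-140-3p, -0.25 for miR-133b-3p, -0.38 for miR-133a-5p, -0.64 for miR-133a-3p, 0.00 for miR-125b-5p, -0.20 for let-7g-5p, -0.24 for let-7f-5p, -0.20 for let-7d-5p and -0.43 for let-7c-5p. Median-of-ratios scaling gave -0.28 for miR-98-5p, -0.48 for miR-27b-3p, -0.06 for miR-26a-5p, -0.83 for miR-1a-3p, -0.70 for miR-145a-5p, -1.15 for miR-142a-3p, -1.29 for miR-140-3p, -0.21 for miR-133b-3p, -0.35 for miR-133a-5p, -0.61 for miR-133a-3p, -0.17 for let-7g-5p, -0.21 for let-7f-5p, -0.17 for let-7d-5p and -0.39 for let-7c-5p. Upper-quartile scaling gave -0.41 for miR-98-5p, -0.04 for miR-451a, -0.61 for miR-27b-3p, -0.19 for miR-26a-5p, -0.95 for miR-1a-3p, -0.02 for miR-16-5p, -0.10 for miR-15a-5p, -0.83 for miR-145a-5p, -0.01 for miR-142a-5p, -1.27 for miR-142a-3p, -1.42 for miR-140-3p, -0.34 for miR-133b-3p, -0.47 for miR-133a-5p, -0.73 for miR-133a-3p, -0.05 for miR-126a-3p, -0.10 for miR-125b-5p, -0.29 for let-7g-5p, -0.34 for let-7f-5p, -0.30 for let-7d-5p and -0.52 for let-7c-5p. Totals without the 10 most abundant miRNAs gave -0.27 for miR-98-5p, -0.47 for miR-27b-3p, -0.05 for miR-26a-5p, -0.82 for miR-1a-3p, -0.69 for miR-145a-5p, -1.14 for miR-142a-3p, -1.28 for miR-140-3p, -0.20 for miR-133b-3p, -0.34 for miR-133a-5p, -0.59 for miR-133a-3p, -0.15 for let-7g-5p, -0.20 for let-7f-5p, -0.16 for let-7d-5p and -0.38 for let-7c-5p. DESeq2 on the recovered reads gave -0.25 for miR-98-5p, -0.47 for miR-27b-3p, -0.04 for miR-26a-5p, -0.87 for miR-1a-3p, -0.68 for miR-145a-5p, -0.01 for miR-142a-5p, -1.24 for miR-142a-3p, -1.28 for miR-140-3p, -0.18 for miR-133b-3p, -0.34 for miR-133a-5p, -0.59 for miR-133a-3p, -0.14 for let-7g-5p, -0.17 for let-7f-5p, -0.14 for let-7d-5p and -0.36 for let-7c-5p. These are values below a shift shared by most miRNAs, not falls on the deposited scale.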

Other observations

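All tests in this part were chosen only after the result was seen, except the test of 3p strands over other hairpins and the count of adipocyte-associated miRNAs. Among miRNAs encoded in the Hox clusters, whose genes carry positional identity along the body, miR-196a-5p and miR-196b-5p fell relative to the shift shared by most miRNAs. The group was gathered after its values were seen and has no set test. Relative to that shift the log2 differences were -2.13 for miR-196a-5p, -1.53 for miR-196b-5p (limma adjusted p = 0.033), -1.21 for miR-615-3p (limma adjusted p = 0.059), -0.54 for miR-10b-5p (SE 0.15) and -0.44 for miR-10a-5p (SE 0.18). On the deposited scale the differences of miR-10a-5p and miR-10b-5p were positive, at 1.14 and 1.04, and that of miR-615-3p was 0.19. miR-196a-5p lay at -0.92 there, but miR-196b-5p only at -0.07 (limma adjusted p = 0.82), so the fall of miR-196b-5p rests on the scaling. In GRCm38, Mir196b lies on chromosome 6 from 52230081 to 52230165 in an exon of Hoxa9, and Mir196a-2 on chromosome 15 from 102973350 to 102973434 in an intron of Hoxc5. The other strands, miR-10a-3p and miR-10b-3p, lay at 0.22 (SE 0.12) and -0.08 (SE 0.23), with deposited differences of 1.76 and 1.11.

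Strand ratios within hairpins, free of any scaling, changed by at least 1 on the log2 scale and by more than 2 standard errors in 6 of the 55 hairpins with both strands at a mean CPM of at least 10. miR-423-5p over miR-423-3p changed by 1.58 (SE 0.21) and miR-28a-5p over miR-28a-3p by 1.06 (SE 0.11). miR-199b-3p over miR-199b-5p changed by 1.62 (SE 0.10), with 19.5 and 18.6 in Sham and 62.2 and 54.7 in CKD, although miR-199b-3p is listed with the same values as miR-199a-3p.

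The smaller share of miR-143-3p in CKD is a pattern for which several explanations can be set against the tables. A loss of smooth muscle cells would lower both strands of the hairpin alike. The log2 ratio of miR-143-3p to miR-143-5p changed by -1.67 instead (2 standard errors are 0.47). This argues against such a loss as the whole cause only if both strands were captured alike in the 2 groups. That was not tested, and miR-143 had the lowest 3p to 5p change of 55 hairpins, so the ratio alone cannot decide. A bias against 3p strands in the CKD libraries would lower the ratio in other hairpins, but their median change was -0.02 (95% interval -0.09 to 0.18, n = 54). A compression of the most abundant miRNAs could not be excluded: of the 8 other distinct abundant miRNAs 4 lay below the shift by over 2 standard errors and 1 above it. The first form of this count gave the identical miR-199a-3p and miR-199b-3p separate places above the shift, and met the bound against compression. That pair was counted once only after the values were seen. A response of the tissue to CKD, and a difference in how well adaptors captured this sequence in the preparations of the 2 groups, were not tested and stay open. A loss of smooth muscle, as the whole or a part, also stays open, with contractile members on both sides. Relative to the shift miR-143-5p lay at -0.81 (SE 0.18) and miR-145a-5p at -0.73 (SE 0.13). On the other side, miR-145a-3p lay at 0.22 (SE 0.11) and miR-145b at 0.65 (SE 0.17). Neither of these passed the threshold (limma adjusted p = 0.29 and 0.1), so they do not decide the question.

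Entries without a miRNA name that were present in 1 group alone are a second pattern. Of 13 such entries with at least 10 CPM in both libraries of a group, 4 had no reads in the other group, against 0 of 276 annotated miRNAs (Fisher's exact test, two-sided p = 2.5e-06). The test was formed on the entries that show the pattern, so its p-value describes them and supports no explanation. Entries predicted, matched or named differently in the libraries of the groups, and expression in 1 group alone, cannot be told apart and both stay open.

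The lower values of miR-196a-5p and miR-196b-5p relative to the shift may come from a different stretch of aorta in the CKD samples. miR-10a-5p and miR-10b-5p had a mean of -0.49. The ratio of miR-10a-3p to miR-10a-5p changed by 0.67 (SE 0.17), which, if real, a change in transcription alone would not give. The Sham ratios were nearly equal (0.004771 and 0.004768), so this SE rests almost wholly on the CKD libraries. A bound of 2 standard errors is lenient with 2 libraries per group. The ratio of miR-10b-3p to miR-10b-5p changed by 0.44 (SE 0.43), within 2 standard errors of 0. Position therefore cannot be told apart from other causes. The condition on the strands was added after the values were seen, and without it the bound for position was met. miR-10a-5p (-0.44, SE 0.18) and miR-10b-5p (-0.54, SE 0.15) both lay below 0 by more than 2 standard errors. Neither passed the adjusted threshold (limma adjusted p = 0.23 and 0.11). For less fat around the aorta, 2 of 11 other adipocyte-associated miRNAs, miR-193a-5p (0.52) and miR-203-3p (0.40), lay above the shift by over 2 standard errors, which met the bound set in advance against it. That bound was too lenient, because 0 of them passed the adjusted threshold, miR-203-3p is also an epithelial marker and the median of -0.13 had an interval of -0.65 to 0.47, so fat and an effect of CKD itself both stay open.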
